A study of Bos taurus with 6 samples.

How the data were processed

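Single-cell RNA sequencing was performed by the authors on Longissimus dorsi muscle of heifer calves aged 4 months. The breeds were full-blood Wagyu, purebred Brahman and a 50/50 crossbred of both, with 2 animals each. Per the labels, muscle pieces were digested at 37 °C for 1 h with the enzymes Dispase II and collagenase D and strained at 100 µm, after which debris and dead cells were depleted. The 3' libraries were made with a droplet kit that tags each transcript with a unique molecular identifier (UMI), and the stated depth was over 20000 read pairs per cell. The submitters' processing notes name Cell Ranger 6.0.0, Seurat 4.0.4 and the taurine genome build ARS-UCD1.2, without settings. Reads from a sequence that differs from that build, or that near-identical gene copies share, can be lost or split by such counting. The values of OAS1Y, OAS1X, OAS1Z, MX1, MX2, the BOLA genes, RPL15 and SYT4 are uncertain for that reason.

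The deposited expression matrix holds natural log values, the log of 1 plus the UMIs of a gene per 10000 UMIs of the cell. Every cell summed to 10000 after the log was undone. Multiplied by the deposited UMI count of the cell, 100% of the 42477365 values above 0 gave whole UMIs within a tolerance of 0.001. The matrix has 16162 genes, of which 14393 carry a symbol and 1769 an Ensembl identifier, in 32708 cells that passed the authors' quality control. CEBPA is not among its genes. The deposited annotation gives each cell its library and 1 of 21 classes, and a further deposited matrix repeats 11249 of the 11892 FAP-1 and FAP-2 cells with 0 values that differ. Gene names are those of the matrix. No annotation of that build was used, so no positions are given, and in a gene table of the later build ARS-UCD2.0 14217 of the 14393 symbols and 0 of the 1769 Ensembl identifiers were found, so genes with an identifier alone stay unnamed. Some single genes are not reported here. Class names are those of the deposited annotation, which does not expand its abbreviations. Cells discarded by the authors, raw reads and unfiltered droplets were not used here, so free RNA was judged from marker genes in cells that should lack them.

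Libraries keep the names in the cell names: C1 and C6 are Wagyu, C2 and C5 crossbred, and C3 and C4 Brahman. The cell names give the breed but not which labelled animal a library came from, so the 2 libraries of a breed were treated as its replicates. The cell counts in the files equal those that the labels state for each breed. No sequencing batch or day is given, so none could be entered as a term.

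For each library and class, UMIs per 10000 were averaged over cells, and 0.1 was added before log2. This scale understates fold changes of genes whose mean lies near or under 0.1 per 10000. Genes with a mean of at least 0.05 per 10000 over the 6 libraries were tested in classes with at least 20 cells in each library, which left FAP-1, Non-VEndoC, FAP-2, Granulocyte-1, CD3 T cell and LEndoC. limma 3.58.1 (lmFit, then eBayes with a trended prior variance) was fitted to all 6 libraries, with two-sided tests and Benjamini-Hochberg adjustment within each class and contrast, at a threshold of 0.05. Contrasts were Wagyu against Brahman, Wagyu against crossbred, crossbred against Brahman, and crossbred against the mean of the pure breeds. The difference of the Wagyu-Brahman effect between FAP-1 and Non-VEndoC was tested with limma on the within-library difference of both classes.

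In FAP-1 and FAP-2, 22 gene lists were tested with limma's camera: adipogenic regulators, lipid uptake and storage, fibrillar collagen and matrix, collagen processing, matrix degradation, TGF-beta pathway, myogenic regulators, sarcomere, interferon response, antigen presentation, chemokines, complement, immediate early response, heat shock, oxidative phosphorylation, mitochondrially encoded genes, glycolysis, cytosolic ribosome, cell cycle, angiogenesis, Wnt and Hedgehog, and IGF. The same lists were tested in the 4 other classes where at least 5 members were measured, as were lists of cell type markers. camera ran with a preset correlation of 0.01 and again with a correlation estimated from the residuals, and fry, which asks whether a list moves on balance in 1 direction, was run beside it. Class shares were compared by exact permutation tests, two-sided, over the 6 arrangements of 2 against 2 libraries, for which the smallest p is 0.3333. Intervals on shares of single libraries are exact binomial at 95%. Ratios against a breed with 1 to 3 UMIs of a gene are of pooled UMIs, so larger libraries weigh more, and carry 95% counting intervals. Where a breed had 0 UMIs, a lower bound was computed against a floor of 3 UMIs over the cells of that breed. Intervals and floors cover counting error only.

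The tests, contrasts, lists and the rule for named genes were fixed before the data were examined. The rule took genes with a symbol, an adjusted p under 0.05 and both libraries of a breed beyond both of the other. In FAP-1 it named up to 10 genes in each direction, in Non-VEndoC and FAP-2 up to 5, and in every class up to 4 called members of a list. It added genes given whatever their result (in the FAP classes PDGFRA, PPARG, ZNF423, DLK1, FABP4, COL1A1, COL3A1, TGFB1 and LOX, in SC the myogenic genes PAX7, MYF5, MYOD1 and MYOG), and the 5 smallest p where a class had no call. PPARG and FABP4 in FAP-1, and FABP4 in FAP-2, were under the expression filter. The same rule and list tests were applied to the other 3 contrasts after the data were seen.

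Alternatives were other pseudocounts and filters, the mean of the deposited natural log values, centred class means, only the 4 libraries compared, an untrended prior variance, edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0 (Wald test) on summed UMIs, the Wagyu share as a number, the 10% of cells with most UMIs left out as possible doublets, other denominators and marker-based classes for shares, and each library left out in turn. A lone library that is left in a breed is assumed to vary like the others. No doublet caller was run, and how the authors treated doublets is not given in the sources used here. Merged FAP classes, the smaller deposited matrix, FAP-1 against FAP-2, further classes tested without C3, the summed immune share, and the Neutrophil class moved to the non-immune cells were added after seeing the data. R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used, with seed 1.

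The procedure was tested on simulated data with the spread and depth of 3 classes. In simulated FAP-1 (8973 genes), limma recovered 7, 46, 49 and 48 of 50 genes each changed 2-fold, 4-fold, 8-fold and 16-fold. Beside them it made 13 false calls. In simulated Non-VEndoC it recovered 2%, 46% and 78%, so changes of 2-fold in single genes were mostly missed. camera called 0 of the 22 unshifted lists and found the interferon list when it was doubled in each of the 3 classes. Genes were drawn independently of each other there. The simulation therefore cannot show how often camera falsely calls lists whose members are correlated.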

Results

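Transcripts were counted in 32708 single cells from the Longissimus dorsi, the long muscle of the back, of 2 Wagyu, 2 Brahman and 2 crossbred heifer calves. Wagyu is a taurine breed kept for its marbled beef and Brahman an indicine breed, and the series is titled as a study of how the beef of these breeds differs in quality. The files hold 120134286 UMIs, with a median of 3070 per cell and a range from 498 to 33313. Of the Wagyu libraries, C1 had 7491 cells and 32589650 UMIs and C6 had 4274 cells and 10536372 UMIs. Of the crossbred libraries, C2 had 8135 cells and 31003973 UMIs and C5 had 6905 cells and 24803114 UMIs. Brahman library C4 had 5434 cells and 19448655 UMIs, whereas C3 had 469 cells and 1752522 UMIs. The median depth per cell was lowest in C6 (1773.5 UMIs) and highest in C1 (3697 UMIs).

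The cells fall into 21 classes, of which FAP-1 (8892 cells) and FAP-2 (3000 cells) carried the matrix transcript DCN at 188 and 238 UMIs per 10000. Non-VEndoC (4379 cells) and VEndoC (1247 cells) carried the endothelial junction gene CDH5 at 8.45 and 3.34, and LEndoC (1036 cells) the lymphatic endothelial gene LYVE1 at 36.1. Granulocyte-1 (2942 cells) carried S100A8, a granulocyte protein, at 123, MuC-1 (1470 cells) the contractile gene ACTA2 at 51.7, and SC (1404 cells) the myogenic factor MYF5 at 4.69. By the fixed markers, 83% of the deposited FAP-1 and FAP-2 cells scored as fibroblast-like, and 98.8% of the cells that scored so lay in those classes. The FAP-1 averages of any 2 libraries correlated across genes at 0.927 to 0.976, where genes are not independent replicates.

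The first question was whether the cell composition of the muscle differed between breeds. FAP-1 and FAP-2 together made up 39.2% ± 4.48 of cells in Wagyu, 44.7% ± 8.56 in Brahman and 29.2% ± 16.9 in crossbred muscle (SD, n = 2 each). The crossbred value spans 17.3% in C2 and 41.2% in C5. Wagyu lay 5.47 percentage points below Brahman (exact permutation, two-sided p = 0.6667, n = 2 per breed), 9.97 points above crossbred (p = 0.6667) and crossbred 15.4 points below Brahman (p = 0.6667), none larger than the spread between libraries. Among cells that are not immune, Wagyu lay 15.6 points below Brahman without overlap (48.7% ± 5.58 and 64.3% ± 13.7, exact permutation p = 0.3333, n = 2). With the Neutrophil class, described below, counted as not immune, the libraries overlapped (Brahman 61.1% ± 18.2, exact permutation p = 0.6667, n = 2). FAP-1 alone was 28.8% ± 5.9 in Wagyu, 34.5% ± 1.71 in Brahman and 23% ± 20.7 in crossbred muscle, and FAP-2 was 10.4% ± 1.42, 10.2% ± 6.85 and 6.22% ± 3.78. FAP-1 did not overlap between Wagyu and Brahman, with 33.3% in C3 just above 33% in C1, nor FAP-2 between Wagyu and crossbred (exact permutation p = 0.3333 for both, n = 2). Non-VEndoC was 17.6% ± 7.28 in Wagyu, 9.72% ± 8.28 in Brahman and 13.7% ± 15 in crossbred muscle (Wagyu against Brahman, exact permutation p = 0.6667, n = 2). LEndoC was 4.33% ± 1.02 in Wagyu and 3.58% ± 3.08 in Brahman muscle (exact permutation p = 1, n = 2), and without C4 the difference of 0.747 points became -1.43. The FAP difference between Wagyu and Brahman became 0.585 points without C4, -11.5 without C3, -8.63 without C1 and -2.31 without C6. That between Wagyu and crossbred became -1.99 without C2 and 21.9 without C5, and that between crossbred and Brahman -3.49 without C2, -27.4 without C5 and -9.38 without C4. No 2 against 2 comparison can give an exact p below 0.3333, which is also the share of arrangements that separate fully by chance.

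The classes named as immune, summed after the data were seen, together made up 40.7% ± 10.9 of cells in crossbred, 30.5% ± 1.48 in Brahman and 19.6% ± 0.0141 in Wagyu muscle (SD, n = 2), without overlap between any 2 breeds (exact permutation p = 0.3333 for each, n = 2). In C3, 44 of these 138 cells are of the Neutrophil class, found only there. By the fixed markers 43 scored as myofibre, yet the class also carried neutrophil genes, so its nature is open. Without that class, a further such step, the share of C3 fell from 29.4% to 20%, beside 19.6% in C1 and 19.5% in C6, while C4 stayed at 31.5%. Brahman then averaged 25.8% ± 8.1, and the difference of Wagyu from Brahman went from -10.9 to -6.23 percentage points, less than the Brahman spread. The distance of crossbred from Brahman, 10.3 points, became 15 without that class, 17.9 without C2 and 2.6 without C5. The named CD8 T cell class, cytotoxic lymphocytes, was 5.22% ± 2.98 of cells in crossbred, 0.249% ± 0.0121 in Wagyu and 0.0644% ± 0.0911 in Brahman muscle, again without overlap (exact permutation p = 0.3333 for each, n = 2). It held 253 cells in C2, 506 in C5, 18 in C1, 11 in C6, 7 in C4 and 0 of 469 in C3, which allows up to 0.64%. CD3 T cells were 10.7% ± 5.44 in Brahman and 2.84% ± 1.27 in Wagyu muscle, and B cells 2.76% ± 0.286 and 1.08% ± 0.136. Granulocyte-1 was 12.8% ± 2.97 in crossbred, 7.49% ± 0.0248 in Wagyu and 3.8% ± 1.86 in Brahman muscle. MuC-1 was 5.64% ± 1.49 in Wagyu and 1.33% ± 0.236 in Brahman muscle, and VEndoC 5.7% ± 0.606 and 1.36% ± 1.02. Each of these pairs separated fully (exact permutation p = 0.3333, n = 2).

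**Figure D1:**
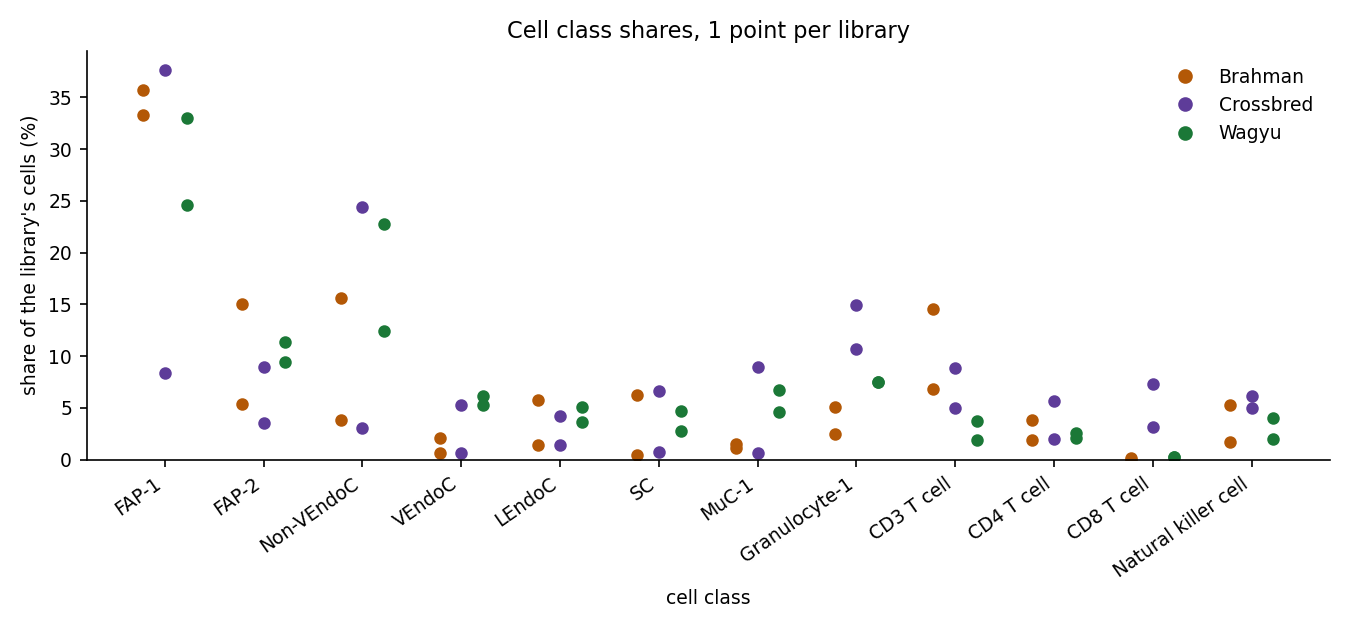
Share of cells in percent (vertical axis) of each library in 12 classes, with 1 point per library coloured by breed. CD8 T cells lie at 5.22% on average in the crossbred libraries and under 0.3% in the others.

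CD8 transcripts were also counted without the class names. The share of T and natural killer cells with a CD8A or CD8B UMI was 24.6% in C2 and 31% in C5, against 12.9% in C1, 13% in C6, 9.78% in C4 and 14.3% (exact 95% interval 5.94% to 27.2%) in C3. In FAP-1 cells, which should lack CD8, the share was 1.92% in C2, 0.693% in C5, 0.972% in C1, 0.475% in C6, 0.774% in C4 and 1.28% in C3. Thinned to 1000 UMIs per cell, the T and natural killer shares were 13.2%, 16%, 5.83%, 6.2%, 3.84% and 4.73% in the same order, and the FAP-1 shares 0.547%, 0.157%, 0.203%, 0.179%, 0.167% and 0.196%. Of the T and natural killer cells with a CD8 UMI, 69.4% in C2 and 75% in C5 were in the CD8 T cell class, against 17.1% in C1, 17.4% in C6, 2.38% in C4 and 0 of 7 in C3, so the class differs more between libraries than CD8 transcripts do. GZMB, a cytotoxic granule protease, had 4001 UMIs in these cells of C5, 252 in C2, 61 in C6, 15 in C1, 11 in C4 and 0 in C3.

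Wagyu and Brahman cells were then compared within classes, the comparison on which the study's title rests. In FAP-1, interferon-induced genes were higher in Wagyu. IFI27, a mitochondrial interferon-induced protein, averaged 4.31 ± 1.84 UMIs per 10000 in Wagyu and 0.176 ± 0.126 in Brahman (SD, n = 2, limma log2 fold change 4.01 ± 0.47 SE, adjusted p = 0.0114). ISG15, a ubiquitin-like antiviral modifier, averaged 1.42 ± 0.222 and 0.0655 ± 0.0394 (3.21 ± 0.27, limma adjusted p = 0.00151, n = 2). IFI6, another interferon-induced mitochondrial protein, averaged 20.2 ± 1.91 and 3.02 ± 0.571 (2.71 ± 0.32, limma adjusted p = 0.0114, n = 2). OAS1Y, a sensor of viral RNA, averaged 1.83 ± 0.383 and 0.206 ± 0.0821 (2.67 ± 0.28, limma adjusted p = 0.00613, n = 2). SYT4, a synaptotagmin of vesicle traffic, averaged 2.07 ± 1.02 in Wagyu against 3 UMIs in all Brahman FAP-1 cells, a ratio of 441 (95% counting interval 151 to 2141; limma adjusted p = 0.000746). RPL15, a protein of the large ribosomal subunit, averaged 11.4 ± 3.1 and 2.27 ± 0.0757 (2.25 ± 0.28, limma adjusted p = 0.0148, n = 2). PON3, a lactonase, averaged 0.257 ± 0.0656 in Wagyu against 1 Brahman UMI, a ratio of pooled UMIs of 207 (counting interval 37 to 8210, limma adjusted p = 0.0367).

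These were the 7 of 8973 FAP-1 genes higher in Wagyu by limma, 0 were lower, and 388 had an unadjusted p under 0.05 (edgeR 11 higher and 0 lower, DESeq2 31 higher and 2 lower). The count was 3 without C3, 0 without C4 and 30 without C1. Without C4 the limma adjusted p was 0.0735 for SYT4, 0.0864 for ISG15, 0.225 for OAS1Y and 0.269 for IFI27, IFI6, RPL15 and PON3. Without C3 it was 0.121 for IFI27, 0.284 for IFI6, 0.385 for RPL15 and 0.231 for PON3, and PON3 also lost its call without C2 (0.11), C5 (0.109) and C6 (0.416). Leaving out C3 or C4 leaves 1 Brahman library.

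Regulators of fat and matrix in FAP-1 did not pass the test. PDGFRA, the receptor that marks such progenitors, averaged 7.35 ± 1.82 in Wagyu and 5.96 ± 0.6 in Brahman (limma log2 fold change 0.28 ± 0.26, adjusted p = 0.983, n = 2). The preadipocyte genes ZNF423 and DLK1 differed by 0.06 ± 0.23 and 0.18 ± 0.38, TGFB1 by 0.06 ± 0.28, and LOX, which cross-links collagen, by 0.06 ± 0.22, of which DLK1 became -0.32 and LOX -0.06 without C3, and ZNF423 -0.04 and TGFB1 -0.10 without C6. TGFB1 and LOX were also below 0 by edgeR, at -0.09 each. COL1A1 and COL3A1, the chains of fibrillar collagens, averaged 76.3 ± 26 and 126 ± 59.2 in Wagyu against 169 ± 28.7 and 231 ± 22 in Brahman (-1.18 ± 0.35 and -0.95 ± 0.34, limma adjusted p = 0.887 and 0.983, n = 2). Without C6 COL3A1 lay at -0.45 and PDGFRA at 0.03, and without C1 at -1.44 and 0.53.

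**Figure D2:**
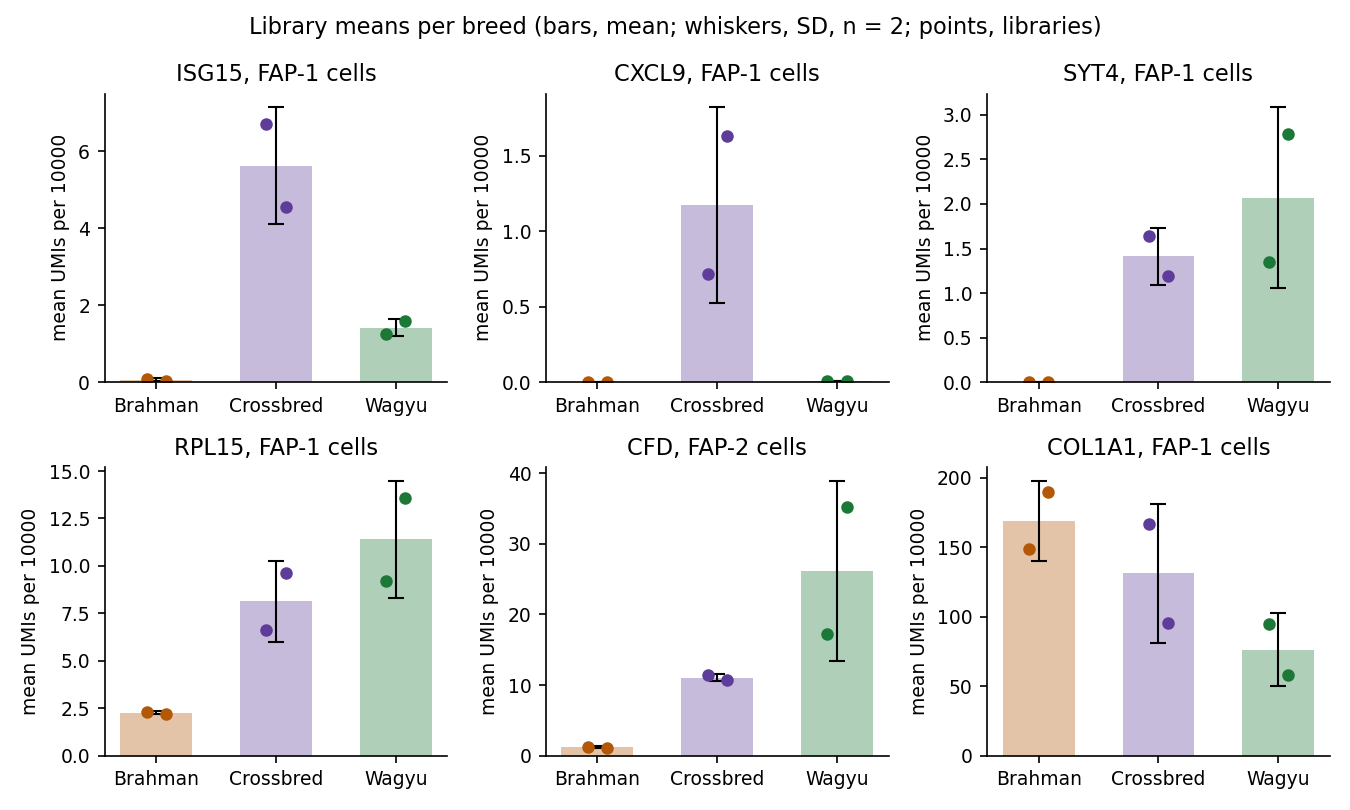
Mean UMIs per 10000 (vertical axis) of ISG15, CXCL9, SYT4, RPL15 and COL1A1 in FAP-1 and of CFD in FAP-2, with points for libraries, bars for breed means and whiskers for the SD (n = 2). Both Brahman libraries lie below the other 4 for SYT4, RPL15, ISG15 and CFD, and the Wagyu mean of COL1A1 is 76.3 against 169 in Brahman.

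As lists, the clearest rise in Wagyu FAP-1 was that of the interferon response. All 21 measured members were positive, at a median log2 fold change of 0.83 (camera adjusted p = 9.6e-28, adjusted p = 0.217 with an estimated correlation). The median was 2.13 by edgeR and 2.33 by DESeq2. With the member at 0 in Brahman at its bound the median was 1.06, and 4 members were called over all genes tested and 13 adjusted over the list alone. An example is MX1, an antiviral GTPase, at 2.46, whereas IRF1 lay at 0.03. Antigen presentation was higher at a median of 0.84 in 8 of 10 members, with 0 called over all genes and 1 adjusted over the list alone (camera adjusted p = 0.000163, adjusted p = 0.617 with an estimated correlation), with the MHC class I light chain B2M at 1.37. Complement was higher at 0.45 in 13 of 14 members (camera adjusted p = 5.1e-05, adjusted p = 0.617 with an estimated correlation), with CFB at 1.70 and C3, the central component, at 1.47. The cytosolic ribosome was higher at 0.28 in 29 of 29 members, 1 of them (RPL15) called over all genes and 1 adjusted over the list alone (camera adjusted p = 2.1e-06, adjusted p = 0.647 with an estimated correlation). The antigen call was lost without C6 (median 0.12, camera adjusted p = 0.0832), and the complement call without C4 (0.0645) and without C6 (0.416, median 0.02).

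Matrix lists were lower in Wagyu FAP-1. Fibrillar collagen and matrix had a median of -0.43, with 8 of 26 members positive (camera adjusted p = 1.6e-05), spanning COL1A1 at -1.18, the matricellular POSTN at -1.02, DCN at 0.03 and TNC at 0.23, and it was -0.14 without C6. Collagen processing lay at -0.28, with 6 of 17 positive (camera adjusted p = 0.0136). The TGF-beta pathway lay at -0.17, with 8 of 26 positive (camera adjusted p = 0.0104). Myogenic regulators, measured through ID2 (-0.86), ID3 (-0.77) and NOTCH3 (-0.68) rather than muscle-specific factors, lay at -0.27, with 1 of 12 positive (camera adjusted p = 0.0238). Immediate early genes, which tissue dissociation induces, lay at -0.34, with 3 of 18 positive (camera adjusted p = 0.00011). IGF genes lay at -0.32, with 3 of 10 positive (camera adjusted p = 0.0484). By edgeR the medians were -0.30 for TGF-beta, -0.59 for the myogenic list, -0.20 for immediate early genes and -0.50 for IGF. With an estimated correlation the adjusted p was 0.217 to 0.647 for these 6 lists. In each of these lists 0 members were called by limma over all genes and 0 adjusted over the list alone. The calls for collagen processing, TGF-beta, myogenic and IGF lists were lost without C4 or C6. That for IGF was also lost without C1, and that for immediate early genes without C4.

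The other lists did not pass camera in FAP-1. Adipogenic regulators had a median of -0.04 (camera adjusted p = 0.385) and lipid uptake and storage -0.02 (0.448), the latter with FASN, the fatty acid synthase, at -0.87 and the fatty acid carrier FABP5 at 0.93. Medians were -0.08 for matrix degradation (0.311), -0.25 for sarcomere (0.318), -0.08 for chemokines (0.562), 0.20 for heat shock (0.311), 0.02 for oxidative phosphorylation (0.745), -0.19 for mitochondrially encoded genes (0.231), -0.07 for glycolysis (0.318) and 0.17 for angiogenesis (0.541). The cell cycle median was 0.03 against a mean of -0.07 (0.541) and -0.22 by edgeR, that of sarcomere was -0.55 by edgeR, and Wnt and Hedgehog had a median of -0.0034 against a mean of 0.09 (0.6). Among these lists 0 members were called over all genes, and adjusted over the list alone 1 member of Wnt and Hedgehog was.

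**Figure D3:**
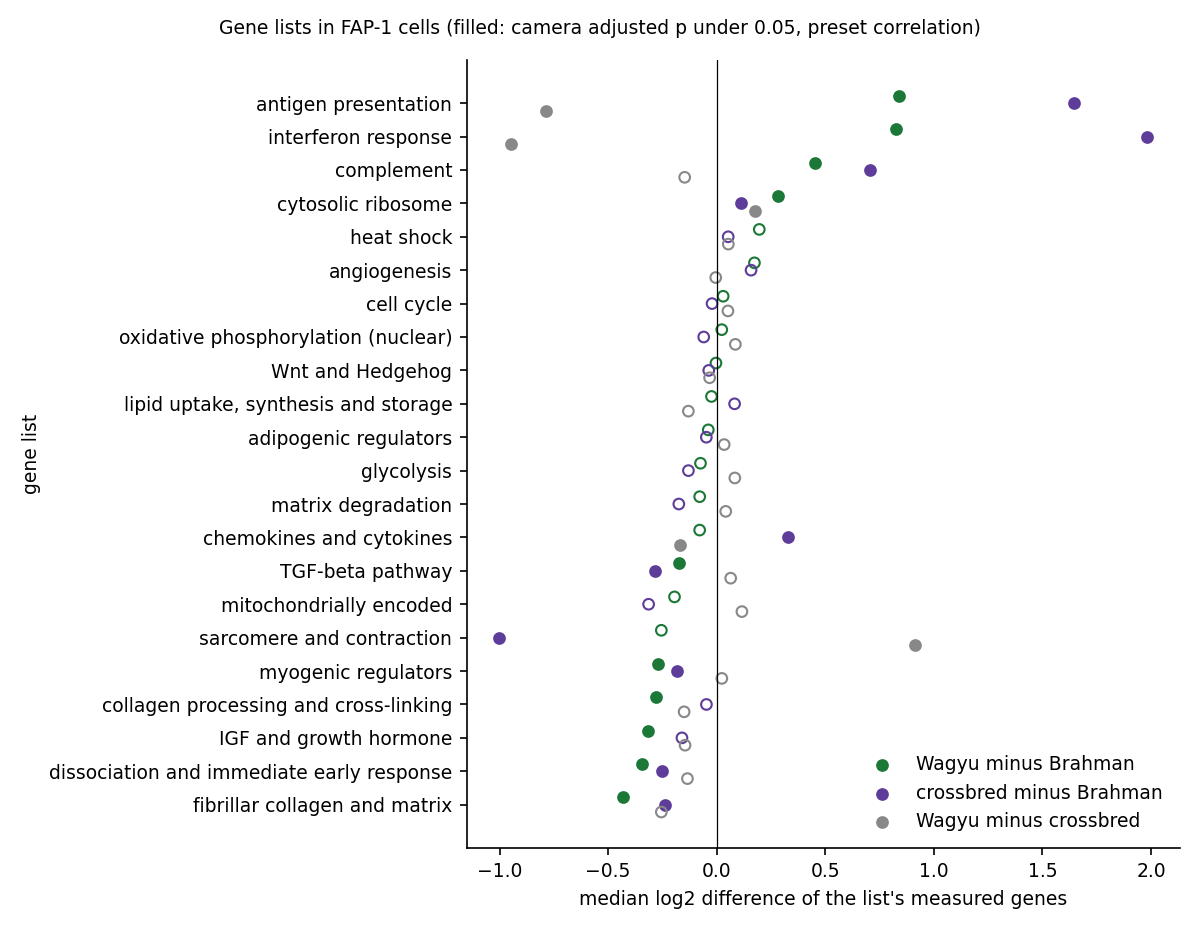
Median log2 fold change (horizontal axis) of 22 gene lists in FAP-1 for Wagyu minus Brahman, crossbred minus Brahman and Wagyu minus crossbred, 1 point per list and comparison, filled where the camera adjusted p with the preset correlation is under 0.05. The interferon list lies at 0.83, 1.98 and -0.95.

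In FAP-2, 4 of 9033 genes were higher in Wagyu than in Brahman by limma and 0 were lower. CFD, complement factor D, which fat cells secrete as adipsin, averaged 26.2 ± 12.7 UMIs per 10000 in Wagyu and 1.21 ± 0.107 in Brahman (SD, n = 2, limma log2 fold change 4.24 ± 0.33 SE, adjusted p = 0.00126). It stayed called with any 1 library left out, as did SYT4, at 2.11 ± 0.308 in Wagyu and 0 UMIs in Brahman, at least 166-fold higher (limma adjusted p = 0.00126, n = 2). ISG15 averaged 0.766 ± 0.331 in Wagyu, a ratio to Brahman of 86.2 (counting interval 23.6 to 716; limma adjusted p = 0.0427), and RPL15 7.35 ± 1.16 against 1.51 ± 0.0783 (2.20 ± 0.27, limma adjusted p = 0.023, n = 2). The ISG15 call was lost without C3 (0.0564), C2 (0.165), C5 (0.15) or C6 (0.684), and that of RPL15 without C2 (0.135), C5 (0.136) or C6 (0.371). PPARG, the master regulator of fat cell formation, differed by 0.25 ± 0.41 (-0.19 without C3, -0.12 by edgeR) and was not called. Nor were PDGFRA (0.16, -0.23 without C3, and -0.03 from the natural log means), ZNF423 (-0.19, 0.12 without C4), DLK1 (-0.89 ± 0.52, -1.70 without C3 and -0.09 without C4) and TGFB1 (0.36, -0.32 without C4). COL1A1 differed by -1.20 ± 0.36 (-0.64 without C6), COL3A1 by -1.08 and LOX by 0.10, all without a call in this fit. COL3A1 was -0.17 without C6 and -1.99 without C1, when it was called (limma adjusted p = 0.0343), as it was from the natural log means (0.00746). Unadjusted, 451 genes had a p under 0.05, edgeR called 9 higher and 1 lower and DESeq2 12 higher and 4 lower. The limma count was 2 without C2, C5 or C6, 7 without C3, 10 without C1 and 1256 without C4, when the 469-cell library C3 stands alone for Brahman. The median of all FAP-2 genes was 0.12 on this scale and 0.0156 by edgeR.

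Of the FAP-2 lists, fibrillar collagen and matrix was lower in Wagyu (median -0.42, 5 of 25 positive, camera adjusted p = 1.5e-05, lost without C6 at 0.379). Mitochondrially encoded genes were lower as well (-0.52, -0.31 by edgeR, 1 of 13 positive, camera adjusted p = 1.7e-06). So was matrix degradation (-0.21, -0.32 by DESeq2, 5 of 13 positive, camera adjusted p = 0.0384, lost without C4 at 0.411 and without C6 at 0.263). The interferon response was higher (0.46, and 2.00 by edgeR and 1.96 by DESeq2, 16 of 20 positive, camera adjusted p = 1.5e-05, lost without C4 at 0.204). The adjusted p with an estimated correlation was 0.855 for each. Over all genes, 1 interferon gene was called and 0 of the others, and adjusted over the list alone 5 interferon genes rose and 1 mitochondrial gene fell.

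CD3 T cells and LEndoC gave 1 and 2 called genes. RPL15 averaged 32.2 ± 14.6 in Wagyu and 3.02 ± 0.529 in Brahman CD3 T cells (limma log2 fold change 3.30 ± 0.31, adjusted p = 0.000574, n = 2), the only call among 7755 genes, with 564 at an unadjusted p under 0.05. In LEndoC, ISG15 averaged 4.24 ± 2.8 and 0.116 ± 0.0114 (4.16 ± 0.44, limma adjusted p = 0.000741, n = 2), and RPL15 was higher by 2.41 ± 0.33 (limma adjusted p = 0.0114, edgeR adjusted p = 0.0791). Both were among 9001 genes, of which 663 had an unadjusted p under 0.05. By edgeR and DESeq2 the counts were 2 and 2 in CD3 T cells and 1 and 3 in LEndoC. Without C6 the limma adjusted p was 0.119 for CD3 T cell RPL15, 0.151 for LEndoC ISG15 and 1 for LEndoC RPL15, and without C3 it was 0.0918, 0.0687 and 0.0687. LEndoC RPL15 also lost its call without C4 (0.115), C2 (0.0784) or C5 (0.0738). The CD3 T cell count was 0 without C3 or C6, 4 without C1, 14 without C2 or C5 and 517 without C4, and the LEndoC count 0 without C3 or C6, 1 without C2 or C5, 4 without C4 and 10 without C1. The median of all LEndoC genes was 0.14, against 0.0429 by edgeR.

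No gene passed in Non-VEndoC or Granulocyte-1. limma called 0 of 8847 Non-VEndoC genes, with 543 at an unadjusted p under 0.05 (edgeR 0, DESeq2 2), and 0 of 5949 Granulocyte-1 genes, with 626 (edgeR 0, DESeq2 12). Of the 5 smallest p in Non-VEndoC, that of IFI47, an interferon-induced GTPase, came with a Wagyu to Brahman ratio of 41.2 (counting interval 7.35 to 1630). The others belonged to IFITM1, which blocks viral entry (at least 7.09-fold), IFI27 (log2 fold change 2.16), MGC139164 (2.38) and DTX3L, a ubiquitin ligase (2.62). The limma adjusted p ran from 0.105 to 0.487. In Granulocyte-1 they belonged to IFITM1 (at least 39.2-fold), OAS1Z (ratio 14.2, counting interval 3.89 to 118), BCAS4 (at least 4.06-fold), the surface protein CD24 (2.88) and the kinase TEC (at least 6.81-fold), at limma adjusted p of 0.204 and 0.334. The Non-VEndoC count was 3 without C3, 5 without C4 and 4 without C1, and the Granulocyte-1 count 1298 without C4. The median of all Granulocyte-1 genes was 0.0036 here and 0.24 by edgeR.

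Interferon genes were higher in Wagyu as a list in these 4 classes as well. The median was 0.86 in Non-VEndoC, with 23 of 25 positive (camera adjusted p = 1.5e-12, adjusted p = 0.525 with an estimated correlation). In Granulocyte-1 it was 2.27, with 25 of 25 positive (camera adjusted p = 1.4e-14, adjusted p = 0.937 with an estimated correlation). In CD3 T cells it was 0.42, with 17 of 20 positive (camera adjusted p = 0.0254, adjusted p = 0.684 with an estimated correlation). In LEndoC it was 1.24, with 21 of 21 positive (camera adjusted p = 6.6e-12, adjusted p = 0.459 with an estimated correlation). With members at 0 at their bound the medians were 2.23 in Granulocyte-1 and 0.86 in LEndoC, where edgeR gave 2.49 and DESeq2 2.54. Over all genes 0, 0, 0 and 1 members were called, and adjusted over the list alone 10, 13, 1 and 7. The CD3 T cell call was lost without C3 (0.0542), C4 (0.15) or C6 (0.189). The LEndoC median was 0.68 without C6, that of Granulocyte-1 1.16 without C3, and that of Non-VEndoC 1.49 without C4 and 1.37 without C1. Antigen presentation was higher in Non-VEndoC, at a median of 0.68 (0.66 at the bound) with 15 of 15 positive (camera adjusted p = 2.9e-05, adjusted p = 0.525 with an estimated correlation). That call was lost without C3 (0.105), and the median was 1.04 without C1. In LEndoC the list lay at 1.61, with 12 of 12 positive (camera adjusted p = 9.9e-09, adjusted p = 0.459 with an estimated correlation), and at 0.95 without C6. Over all genes 0 members were called in either class, and adjusted over the list alone 0 in Non-VEndoC and 8 in LEndoC. PSMB8, a subunit of the immunoproteasome, lay at 2.20 in LEndoC.

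Immediate early genes were lower in Wagyu LEndoC, at a median of -0.98 with 0 of 17 positive (camera adjusted p = 1.2e-12). ATF3, a stress-induced factor, lay at -1.64, and the median was -0.34 without C6 and -1.67 without C1. In Non-VEndoC the list lay at -0.44, with 2 of 18 positive (camera adjusted p = 0.000295), a call lost without C4 (0.24) or C6 (0.409). LEndoC complement was higher (0.58, 0.92 by edgeR, 8 of 9, camera adjusted p = 0.00833, lost without C3 at 0.0963). Its myogenic list was lower (-0.74, -0.33 by edgeR, 3 of 10, camera adjusted p = 0.0182). So was its matrix degradation list (-0.21, 4 of 11, camera adjusted p = 0.0478). Heat shock genes were lower by a median of -0.18 (1 of 12, camera adjusted p = 0.033). The myogenic call was lost without C3 (0.206), C4 (0.0664) or C6 (0.287), and the heat shock call without C3 (0.206, median 0.35) or C6 (0.884, median 0.06). The matrix degradation call was lost without C4 (0.676, median 0.17), C1 (0.0548) or C6 (0.131). With an estimated correlation the adjusted p was 0.459 to 0.889 for these 6 tests. Over all genes 0 members of these lists were called, and adjusted over the list alone 4 immediate early and 1 matrix degradation gene fell and 3 complement genes rose, all in LEndoC.

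In Non-VEndoC, matrix genes (median -0.47, 5 of 21 positive, camera adjusted p = 0.00338, adjusted p = 0.594 with an estimated correlation) and mitochondrially encoded genes (-0.55, 1 of 13, camera adjusted p = 9.4e-05, adjusted p = 0.525 with an estimated correlation) were lower in Wagyu. Without C6 both calls were lost (the mitochondrial median then being 0.05), the first also without C3 and the second without C4. The ribosome list lay at -0.18 (5 of 29, camera adjusted p = 0.0346, adjusted p = 0.688 with an estimated correlation) but at 0.17 by edgeR and 0.09 by DESeq2, and at 0.05 without C6. In CD3 T cells, matrix genes were lower (-0.78, 1 of 16), and oxidative phosphorylation (0.35, 21 of 24) and ribosome genes (0.15, 0.22 by edgeR, 25 of 29) were higher. All 3 had a camera adjusted p = 0.00545 and an adjusted p = 0.684 with an estimated correlation. The matrix and oxidative phosphorylation calls were lost without C6, the matrix call also without C3, and the ribosome call without C3 (median -0.03) or C1. By limma, 0 members of these lists were called over all genes except RPL15 in CD3 T cells. Adjusted over the list alone, 2 mitochondrial genes fell and 1 ribosome gene rose in Non-VEndoC, and 1 ribosome gene rose in CD3 T cells. Of all 32 list calls between Wagyu and Brahman, 0 held with an estimated correlation, the smallest adjusted p being 0.217, and 0 passed fry, the smallest being 0.0747. In the other 3 contrasts fry passed 0 of 36 camera calls between Wagyu and crossbred, 1 of 43 between crossbred and Brahman and 1 of 44 against the mean of the pure breeds, both times the FAP-1 interferon list.

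Lists of cell type markers also moved with the breeds, but the fibroblast markers are not independent of the matrix list. DCN, LUM, COL1A1, COL1A2 and COL3A1 belong to both. Fibroblast markers were lower in Wagyu in FAP-1 (median -0.33, camera adjusted p = 0.00631) and FAP-2 (-0.32, camera adjusted p = 0.00446). They were also lower in classes that should lack them, Non-VEndoC (-0.98, camera adjusted p = 0.00423) and CD3 T cells (-1.24, camera adjusted p = 0.00305). Tenocyte markers were lower in FAP-1 (-0.46, camera adjusted p = 0.0184). Blood endothelial markers were higher in FAP-2 (0.67, camera adjusted p = 0.0285) and LEndoC (0.49, camera adjusted p = 0.0484). With an estimated correlation the adjusted p was 0.151 to 0.59 for these 7 tests. Blood endothelial and myofibre lists each held 1 member adjusted over the list alone, in LEndoC and Granulocyte-1, and 0 members of any marker list were called over all genes. The other 16 marker tests in these classes gave camera adjusted p from 0.0512 to 0.747.

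The Wagyu-Brahman effect itself was compared between FAP-1 and Non-VEndoC. limma called 0 of 7799 genes as different between these classes, with 415 at an unadjusted p under 0.05 (no other tool was run), and 168 without C4. So the 7 genes called in FAP-1 and 0 in Non-VEndoC are not shown to differ in effect. Merging FAP-1 and FAP-2, a step added after seeing the data, gave 5 genes higher in Wagyu, all among the 7 of FAP-1.

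In SC, the class with myogenic genes, C3 held 2 cells, so values are given for the other 5 libraries. PAX7, the satellite cell factor, averaged 0.283 UMIs per 10000 in C4, 0.366 in C1, 0.454 in C6, 0.114 in C2 and 0 over 49 cells in C5. MYF5 averaged 4.95 in C4, 6.86 in C1, 5.55 in C6, 2.97 in C2 and 4.3 in C5. MYOD1, which commits cells to muscle, averaged 0.968, 1.14, 1.96, 1.07 and 0.506 in the same order, and MYOG, which drives their differentiation, 1.77, 1.5, 3.08, 5.55 and 0.134.

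The crossbred calves show where animals with both parental breeds lie. Against Wagyu, limma called 2 chemokines that draw T cells, CXCL9 and CXCL10, and MX2 in FAP-1. CXCL9 averaged 1.17 ± 0.647 UMIs per 10000 in crossbred, 0.0102 ± 0.000716 in Wagyu and 0 in Brahman FAP-1 (SD, n = 2, limma log2 fold change Wagyu minus crossbred -3.43 ± 0.32 SE, adjusted p = 0.00661). CXCL10 averaged 0.795 ± 0.0297 and 0.0932 ± 0.0855 (-2.29 ± 0.30, limma adjusted p = 0.0439, edgeR 0.619, DESeq2 1, n = 2), and MX2, an antiviral GTPase, differed by -2.15 ± 0.24 (limma adjusted p = 0.0175, edgeR 0.0778). In FAP-2, CXCL9 averaged 2.44 ± 0.791 in crossbred against 2 Wagyu UMIs, a ratio of 610 (counting interval 168 to 5042; limma adjusted p = 0.00434). The FAP-1 CXCL9 call was lost without C3 (0.0841) or C4 (0.0836), and the FAP-2 call without C2 (0.0656) or C5 (0.178). CXCL10 lost its call without C3, C4, C2, C5 or C6 (0.0503 to 0.348) and MX2 without C3, C4, C2, C5 or C1 (0.0716 to 0.217).

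These 3 genes in FAP-1 and 1 in FAP-2, all lower in Wagyu, were the limma calls between Wagyu and crossbred, with 173 and 108 genes at an unadjusted p under 0.05 (edgeR 1 and 1, DESeq2 15 and 6). By limma, 0 genes were called in Non-VEndoC, Granulocyte-1, CD3 T cells and LEndoC, with 103, 21, 47 and 103 at an unadjusted p under 0.05 (edgeR 5, 0, 0 and 1, DESeq2 7, 0, 0 and 2). The FAP-1 count was 0 without C3 or C4 and 11 without C6, and the FAP-2 count 0 without C2 or C5 and 2 without any of the others. Interferon genes were lower in Wagyu FAP-1 as a list (median -0.95, 0 of 21 positive, 1 called over all genes and 15 adjusted over the list alone, camera adjusted p = 2.4e-44, adjusted p = 0.183 with an estimated correlation, -0.63 without C2). In FAP-2 the median was -1.17 (2 of 20, camera adjusted p = 8.8e-29, adjusted p = 0.401 with an estimated correlation, 0 called and 10 adjusted over the list alone, -0.69 without C2). In LEndoC it was -1.002 (0 of 21, camera adjusted p = 1e-23, adjusted p = 0.46 with an estimated correlation), with 0 called and 6 adjusted over the list alone, and -0.65 without C2 and -0.55 without C1. In Non-VEndoC it was -0.54 (0 of 25, camera adjusted p = 1.1e-12, adjusted p = 0.491 with an estimated correlation), with 0 and 0, and -0.30 without C2, -0.28 without C1 and -0.94 without C5. In Granulocyte-1 it was -0.51 (-0.31 by DESeq2, 1 of 25, camera adjusted p = 9.1e-07, adjusted p = 0.624 with an estimated correlation) and in CD3 T cells -0.27 (5 of 20, camera adjusted p = 0.00361, adjusted p = 0.822 with an estimated correlation), with 0 and 0 in both. These calls were lost without C1 (0.912 and 0.441), the second also without C2 (0.426), where the first median was -0.23. By edgeR the median was -0.97 in Non-VEndoC and -0.56 in CD3 T cells. The fixed chemokine list, without CXCL9 and CXCL10, had a FAP-1 median of -0.17 (-0.36 by edgeR, 3 of 14, camera adjusted p = 0.0011, adjusted p = 0.289 with an estimated correlation), with 0 called and 3 adjusted over the list alone. It was -0.02 without C6 (camera adjusted p = 0.0849), -0.10 without C2, -0.29 without C5 and -0.37 without C1. Sarcomere genes, which FAP-1 cells should not make, were higher in Wagyu FAP-1 (0.91, 19 of 19, camera adjusted p = 2.2e-08, adjusted p = 0.874 with an estimated correlation, lost without C2 at 0.511), with 0 called and 0 adjusted over the list alone. The myofibre actin ACTA1 averaged 3.6 there in C1 and 3.96 in C6, against 0.492 in C2 and 2.33 in C5.

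Crossbred against Brahman gave the most calls, and 13 of the 38 in FAP-1 belonged to the interferon list. In FAP-1, ISG15 averaged 5.63 ± 1.51 in crossbred and 0.0655 ± 0.0394 in Brahman (SD, n = 2, limma log2 fold change 5.11 ± 0.27 SE, adjusted p = 3.4e-05). IFI27 was higher by 5.70 ± 0.47 and IFI6 by 4.10 ± 0.32 (limma adjusted p = 0.000419 for both), CXCL9 at least 531-fold (limma adjusted p = 0.000553) and MX2 at least 191-fold (limma adjusted p = 0.000419). CXCL10 (3.07 ± 0.30), OAS1Y (3.27) and RSAD2, an antiviral enzyme (2.64 ± 0.24), kept their calls with any 1 library left out, as did the preceding 5. SYT4 was higher by a ratio of 344 (counting interval 117 to 1668; limma adjusted p = 0.000419), MX1 by 3.24 ± 0.38 (limma adjusted p = 0.0048), and RPL15 by 1.77 ± 0.28 (limma adjusted p = 0.0268). B2M averaged 41.5 ± 2.29 and 6.86 ± 0.445 (2.58 ± 0.38, limma adjusted p = 0.0162, n = 2), with PSMB9 of the immunoproteasome at 2.58 (limma adjusted p = 0.0271) and the complement gene C2 at 1.252 ± 0.22 (limma adjusted p = 0.0425). KLK10, a secreted serine protease, was lower, at 0.117 ± 0.00964 against 0.61 ± 0.0287 (-1.71 ± 0.22, limma adjusted p = 0.00688, n = 2). Without C3 the calls were lost for MX1 (0.121, and 0.0527 without C4) and KLK10 (0.0799, 0.0699 without C2 and 0.0766 without C5). Those of RPL15 (0.0672 to 0.365), B2M (0.118 to 0.387), PSMB9 (0.104 to 0.404) and the complement gene (0.0972 to 0.391) were lost without C3, C4, C2 or C5.

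In all, limma called 36 FAP-1 genes higher and 2 lower in crossbred than in Brahman, with 383 at an unadjusted p under 0.05 (edgeR 41 and 2, DESeq2 70 and 7). The count was 12 without C3, 20 without C2, 24 without C5 and 67 without C1 or C6. In FAP-2 it called 11 higher and 0 lower, with 417 unadjusted (edgeR 24 and 1, DESeq2 21 and 2). Among them were ISG15 (ratio 622, counting interval 172 to 5143; limma adjusted p = 0.00101) and CXCL9 (at least 263-fold, limma adjusted p = 0.00199). IFI27 was higher by a pooled ratio of 790 (counting interval 270 to 3834, limma adjusted p = 0.0087). MX1 rose by 3.88 (limma adjusted p = 0.00966) and OAS1Y by 3.73 (limma adjusted p = 0.0087). CFD averaged 11.1 ± 0.531 against 1.21 ± 0.107 (3.09 ± 0.33, limma adjusted p = 0.00853, n = 2). RPL15 was higher by 1.96 (limma adjusted p = 0.0175). Calls were lost without C2 for IFI27, CFD, MX1, OAS1Y and RPL15, without C5 for CFD and RPL15 and without C3 for RPL15. The FAP-2 count was 2 without C2, 6 without C5 and 1404 without C4. The merged FAP classes gave 22 higher and 1 lower, of which 22 were among those of FAP-1.

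LEndoC gave 24 genes higher and 0 lower in crossbred than in Brahman (711 unadjusted, edgeR 20 higher and 5 lower, DESeq2 22 and 6). ISG15 averaged 10.4 ± 4.06 against 0.116 ± 0.0114 (5.55 ± 0.44, limma adjusted p = 1.4e-05, n = 2) and kept its call with any 1 library left out. IFI27 was higher by 5.63 ± 0.65 (limma adjusted p = 0.00122, 0.178 without C2) and MX1 by a ratio of 126 (counting interval 22.5 to 4991; limma adjusted p = 0.00348). IFI6 was higher by 4.51 and CD74, the MHC class II chaperone, by 3.19 ± 0.43 (limma adjusted p = 0.00348 for both). RPL15 was higher by 2.32 (limma adjusted p = 0.00439, 0.247 without C2), and without that library MX1, IFI6 and CD74 lay at 0.248. Of MHC genes, the class II chain BOLA-DRA was higher by a ratio of 44.3 (counting interval 12.2 to 367; limma adjusted p = 0.00581), and the class I gene BOLA by 4.28 ± 0.69 (limma adjusted p = 0.0093, edgeR 0.079). PSMB8 was higher by 3.23 (limma adjusted p = 0.0296, edgeR 0.193). Without C2 the adjusted p of these 3 genes was 0.618, 0.508 and 0.783. Further calls were lost without C3 (MX1 0.129, CD74 0.0634, BOLA-DRA 0.0708, BOLA 0.288, PSMB8 0.266), without C4 (IFI6, CD74 and RPL15 0.0707, BOLA-DRA 0.0699) and without C5 (RPL15 and BOLA 0.106, PSMB8 0.328). BOLA-DRA and PSMB8 also lost theirs without C1 (0.067 and 0.152) or C6 (0.0568 and 0.146). The LEndoC count was 7 without C3, 14 without C4, 1 without C2, 13 without C5, 12 without C1 and 11 without C6, and the median of all its genes was 0.11, against 0.0457 by edgeR.

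The other classes gave few calls between crossbred and Brahman. In CD3 T cells 3 genes were higher and 0 lower (418 unadjusted, edgeR 7 higher and 4 lower, DESeq2 4 and 0). They were RPL15 (3.08 ± 0.31, limma adjusted p = 0.00131, 0.151 without C3), IFI6 (2.66 ± 0.37, limma adjusted p = 0.0233, 0.541 without C3, 0.202 without C1 and 0.196 without C6) and IFITM1 (3.55 ± 0.52, limma adjusted p = 0.0297), the last outside the rule and chosen after its values were seen. Non-VEndoC gave IFI47 (ratio 113, counting interval 20.2 to 4464; limma adjusted p = 0.021, 0.309 without C2, 0.22 without C5, edgeR 0.134), the only 1 of 8847 genes, with 756 unadjusted (edgeR 0, DESeq2 11 higher and 4 lower). By limma, 0 genes were called in Granulocyte-1, with 548 unadjusted (edgeR 0, DESeq2 14 and 1), where the median of all genes was -0.04 here and 0.27 by edgeR. The CD3 T cell count was 0 without C3, 1 without C6, 2 without C1, 9 without C5, 20 without C2 and 487 without C4, the Non-VEndoC count 5, 2, 2, 0, 0 and 166, and the Granulocyte-1 count 1346 without C4.

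The interferon list was higher in crossbred than in Brahman cells in each of the 6 classes by camera with the preset correlation, and in none of them with an estimated correlation. In FAP-1 its median was 1.98, with 21 of 21 members positive, 13 called over all genes and 20 adjusted over the list alone (camera adjusted p = 1.6e-63, adjusted p = 0.109 with an estimated correlation, fry 0.0277). By edgeR and DESeq2 the FAP-1 median was 3.81 and 3.78, that of FAP-2 4.03 and 4.005 and that of LEndoC 4.89 and 4.03. The summed level of the list in FAP-1 was 118 UMIs per 10000 in C2 and 63.1 in C5, against 30.3 in C1, 36.3 in C6, 5.24 in C4 and 6.3 in C3. In FAP-2 the median was 1.92, with 6 called and 13 adjusted over the list alone (camera adjusted p = 6.1e-23, adjusted p = 0.273 with an estimated correlation). In LEndoC it was 2.40, with 6 and 18 adjusted over the list alone (camera adjusted p = 9.7e-32, adjusted p = 0.33 with an estimated correlation). In Non-VEndoC it was 1.77, with 0 and 20 (camera adjusted p = 4e-24, adjusted p = 0.46 with an estimated correlation). In Granulocyte-1 it was 2.56, with 0 and 19 (camera adjusted p = 4.4e-22, adjusted p = 0.826 with an estimated correlation). CD3 T cells had the smallest, 0.72, 1.08 by edgeR and 0.26 without C2, with 1 and 3 (camera adjusted p = 2.5e-05, adjusted p = 0.567 with an estimated correlation). Mitochondrially encoded genes, a sign of RNA quality, were lower in crossbred than in Brahman beside it in FAP-2 (-0.92, -0.54 by edgeR, 0 of 13 positive, camera adjusted p = 2.9e-14), in Non-VEndoC (-1.06, 1 of 13, camera adjusted p = 4e-08) and in CD3 T cells (-0.28, -0.04 by edgeR, 0 of 13, camera adjusted p = 0.00237). With an estimated correlation the adjusted p was 0.273 to 0.567. Of these genes 0 were called by limma over all genes, and 9, 5 and 0 fell adjusted over the list alone. The CD3 T cell median was -0.13 without C3, -0.51 without C4 and -0.46 without C2. In FAP-1 it was -0.31 (camera adjusted p = 0.0663). At the bound the interferon medians were 1.88 in Non-VEndoC, 2.53 in Granulocyte-1 and 2.25 in LEndoC.

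Antigen presentation was higher in crossbred than in Brahman FAP-1, at a median of 1.64 with 10 of 10 positive (camera adjusted p = 3.1e-13, adjusted p = 0.291 with an estimated correlation), 2 called over all genes and 6 adjusted over the list alone. In LEndoC it lay at 2.77 with 12 of 12 positive (camera adjusted p = 2.3e-19, adjusted p = 0.411 with an estimated correlation), 6 called and 9 adjusted over the list alone. FAP-1 complement was higher (0.70, 13 of 14, camera adjusted p = 9.8e-08, adjusted p = 0.381 with an estimated correlation), with 1 called and 1 adjusted over the list alone. Its TGF-beta list was lower (-0.28, -0.465 by edgeR, 4 of 26, camera adjusted p = 0.000113, adjusted p = 0.381 with an estimated correlation, -0.58 without C2 and -0.08 without C5), with 0 and 0. Sarcomere genes were lower in FAP-1 (-1.001, -1.60 by edgeR, 0 of 19, camera adjusted p = 7.1e-08, adjusted p = 0.583 with an estimated correlation), with 0 and 0. This turned to 0.24 without C3 and was lost without C2 (0.223). ACTA1 averaged 10.7 UMIs per 10000 in FAP-1 of C3 and 0.856 in C4.

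**Figure D4:**
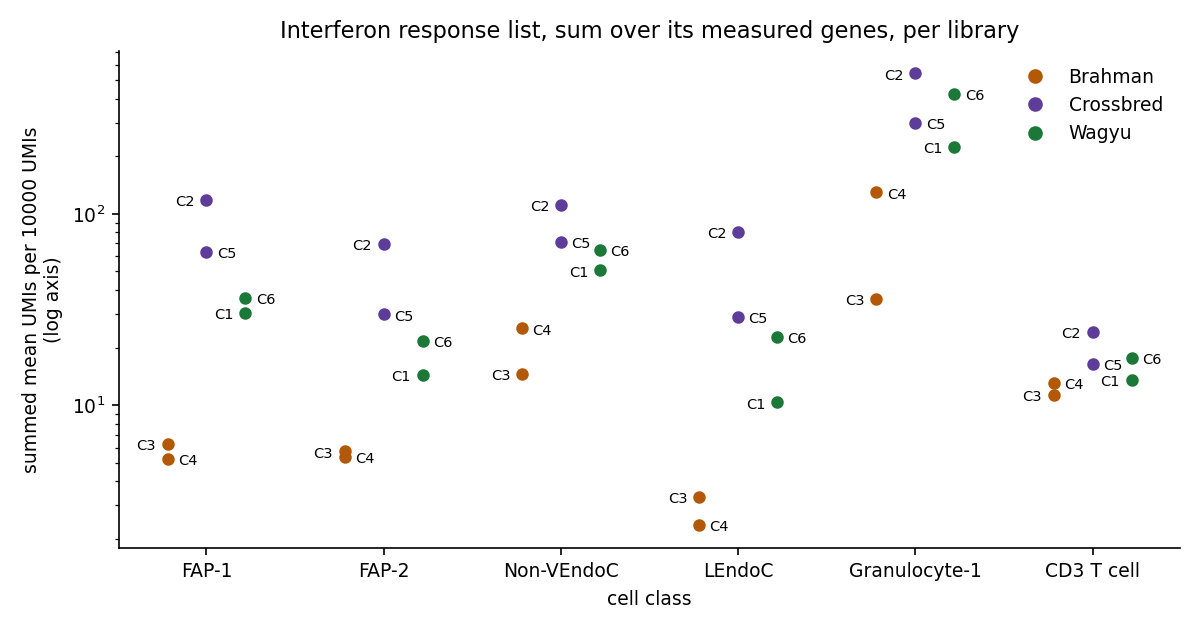
Summed mean UMIs per 10000 of the interferon response list (vertical axis, logarithmic) in each of the 6 tested classes, 1 point per library coloured by breed. In FAP-1 the Brahman libraries lie at 5.24 and 6.3, the Wagyu libraries at 30.3 and 36.3 and the crossbred libraries at 63.1 and 118.

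The crossbred was also compared with the mean of the pure breeds, a test that a value between the 2 parents can pass. In FAP-1, 13 genes were higher than that mean and 0 lower, with 256 at an unadjusted p under 0.05 (no other tool was run on this contrast). Of the 13, only CXCL9, CXCL10 and MX2 were also called above Wagyu, so for the others a place above both parents is not shown. ISG15 lay above it by 3.50 ± 0.24 (limma adjusted p = 0.00033), CXCL9 by 3.50 ± 0.28 (limma adjusted p = 0.0007) and MX2 by 2.48 ± 0.21 (limma adjusted p = 0.000813), each with any 1 library left out as well. IFI27 lay above by 3.69 ± 0.40 (limma adjusted p = 0.0037, 0.0864 without C2 and 0.0566 without C4) and IFI6 by 2.74 (limma adjusted p = 0.00199, 0.0566 without C4). CXCL10 (2.68, limma adjusted p = 0.00171) and RSAD2 (2.05, limma adjusted p = 0.00199) both lay at 0.0538 without C2. OAS1Y (1.94, limma adjusted p = 0.00987) lost its call without C4 (0.0708), C2 (0.228) or C5 (0.056). PARP14 (1.63, limma adjusted p = 0.0347) and EPSTI1 (1.503, limma adjusted p = 0.0402), both interferon-induced, lost theirs without C3, C4, C2 or C5 (0.0616 to 0.41 and 0.0643 to 0.366). Of the 21 list members, 18 were higher in both crossbred than in both Wagyu libraries, and chance alone separates 2 against 2 libraries fully, in either direction, with a probability of 0.3333. The list's median was 1.45, with 7 called and 20 adjusted over the list alone (camera adjusted p = 6.3e-73, adjusted p = 0.0886 with an estimated correlation). The FAP-1 count was 6 without C4, 23 without C1 and 44 without C6.

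In FAP-2, 5 genes lay above the parental mean and 0 below (156 unadjusted), of which only CXCL9 was also called above Wagyu. CXCL9 lay above by 4.61 ± 0.36 (limma adjusted p = 0.00104) and ISG15 by 3.74 (limma adjusted p = 0.00327, 0.259 without C2 and 0.0572 without C5). IFI27 (3.92) and RSAD2 (2.77) did so at a limma adjusted p = 0.0385, and 0.78 without C2. RSAD2 also lost its call without C5 (0.196), C1 (0.115) or C6 (0.0939). The other gene, ENSBTAG00000025258 (4.22, limma adjusted p = 0.044), was outside the rule and chosen after its values were seen. In LEndoC 11 lay above and 0 below (267 unadjusted), including ISG15 (3.47 ± 0.38, limma adjusted p = 0.00122, 0.306 without C2) and IFI27 (4.10, limma adjusted p = 0.0108). IFI6 (3.30) and GBP2, an interferon-induced GTPase (2.77), lay above at a limma adjusted p = 0.0262, and B2M (2.25) and CD74 (2.35) at 0.0251. BOLA (3.28) and BOLA-DRA (2.40) did so at 0.0485. All but ISG15 lost the call in most fits with 1 library left out: BOLA-DRA without any of the 6 (0.107 to 1), GBP2 without any but C4 (0.0823 to 0.375), BOLA without any but C4 (0.106 to 1), IFI6 without any but C3 (0.0518 to 1), B2M and CD74 without any but C6 (0.1 to 1 and 0.114 to 1), and IFI27 without C4, C2, C1 or C6 (0.0504 to 1). By limma, 0 genes were called in Non-VEndoC (326 unadjusted), Granulocyte-1 (117) and CD3 T cells (91). The FAP-2 count was 8 without C3, 13 without C4, 1 without C2, 2 without C5 and 9 without C6, the LEndoC count 3, 7, 1, 2 and 4 in that order and 2 without C1. The Non-VEndoC count was 2 without C3 and 3 without C4, and the CD3 T cell count 1 without C4 or C1, 3 without C2 and 9 without C5.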

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

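The test of granulocyte RNA was written before its result was seen; the other tests here, and the comparison of FAP-1 with FAP-2, were chosen after the results they bear on.

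In FAP-1, interferon-response genes were lowest in Brahman and highest in crossbred cells, with 19 of 21 members lower in both Brahman libraries than in the other 4, but in Granulocyte-1 the list summed to 423 in Wagyu C6 and 297 in crossbred C5, and in CD3 T cells to 17.6 and 16.4. No library alone set the Wagyu-Brahman difference in FAP-1, as its lowest median with 1 left out was 0.7567. Granulocyte RNA would carry at most 1.063% of the summed level in Wagyu and crossbred libraries. Poorer mapping of Brahman reads would not put the crossbred above Wagyu, yet in 18 of 21 members both crossbred exceeded both Wagyu libraries. Nor would it depend on the class, yet the log2 ratio of Wagyu to Brahman was larger in FAP-1 than in CD3 T cells. The median gap was 1.541 over 9 members (8 positive, -0.144 to 4.278). For members outside these 9, such as IFI27 and OAS1Y, poorer mapping in Brahman stays open. A breed difference, infection or other exposure of single animals, and an unrecorded batch were not tested and may each explain the pattern.

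RPL15 was lower in Brahman than in Wagyu FAP-1 cells. Poorer recovery of ribosomal protein transcripts in Brahman would lower the other genes of the list alike, but their median log2 difference between Wagyu and Brahman was 0.2761, against 2.25 for RPL15. A Brahman sequence difference in RPL15, reads shared with copies such as the 1 pseudogene that a gene table of the build ARS-UCD2.0 names after it, and lower expression in Brahman cannot be told apart for this gene. In all 12 other classes with enough cells, Brahman library C4 lay below the 4 Wagyu and crossbred libraries, which is what a sequence difference would give. The crossbred values, at 1.154 to 1.788 times the midpoint of Wagyu and C4, lie above that midpoint, and the genotypes of the parents are unknown.

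The CD8 T cell class lay mostly in the crossbred libraries. Class names that follow the library instead of CD8 transcripts are argued against for the direction of the difference, since the lower crossbred share of T and natural killer cells with a CD8 UMI, thinned to equal depth, was 2.134 times the highest of C4, C1 and C6. For its size such naming has the values it needs, since the share of cells with a CD8 UMI that are in the class was 3.993 times higher in the lower crossbred library than in the highest of those 3, although cells outside the class may differ in state. Free CD8 RNA is argued against too, since thinned FAP-1 cells carried a CD8 UMI at most 4.132% as often as T and natural killer cells in the crossbred libraries. A difference of breed, an immune exposure of the crossbred animals, or the amount of blood in the tissue may lie behind it and was not tested.

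Signals outside the classes compared stood above the limit that a count of 0 allows. Granulocyte-2 carried the fibroblast matrix gene DCN at 108 UMIs per 10000. Proliferating T cells carried HBB, a haemoglobin chain, at 50.9. The Neutrophil class carried ACTA1 at 111 and the neutrophil markers S100A12 at 73.3 and S100A8 at 36.

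Between FAP-1 and Non-VEndoC the Wagyu-Brahman effect differed, by the test of the difference itself, for 2 lists. It was higher in FAP-1 by a median log2 of 0.4052 for mitochondrially encoded genes (camera adjusted p = 0.00979, adjusted p = 0.868 with an estimated correlation) and by 0.4511 for the cytosolic ribosome (camera adjusted p = 3.2e-06, adjusted p = 0.868 with an estimated correlation), the latter 0.1927 by edgeR and 0.2706 by DESeq2. The interferon list did not pass there (-0.1647, camera adjusted p = 0.88), but its median difference was 1.154 by edgeR and 1.239 by DESeq2. Between FAP-1 and FAP-2 it was higher in FAP-1 for interferon response (0.3029, camera adjusted p = 0.000311), antigen presentation (0.4332, camera adjusted p = 0.0137), complement (0.5935, camera adjusted p = 0.0137), mitochondrially encoded genes (0.3434, 0.1201 by edgeR, camera adjusted p = 0.00152) and cytosolic ribosome (0.378, 0.226 by edgeR, camera adjusted p = 2.9e-06). It was lower in FAP-1 for myogenic regulators (-0.8081, camera adjusted p = 0.00721) and immediate early genes (-0.4907, camera adjusted p = 0.0109). With an estimated correlation the adjusted p was 0.477 for the interferon and myogenic lists and 0.751 for the other 5, and fry gave 0.207 or more for all 7 and 0.926 for the 2 against Non-VEndoC. In both comparisons limma called 0 single genes, with 415 and 399 at an unadjusted p under 0.05, and no other tool was run on them.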

How the results depend on the processing

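Merged FAP classes, the smaller deposited matrix, FAP-1 against FAP-2, further classes without C3, non-immune shares with the Neutrophil class moved, and all values of the summed immune share and of lists outside the Wagyu-Brahman contrast were chosen after the data were seen; the other alternatives were fixed before. With 2 libraries per breed, a left-out library leaves 1 that is assumed to vary like the other breeds, and C3, with 469 cells, is then the lone Brahman library when C4 is left out. Of 666 recalculations of called named genes, 474 kept the call and 192 lost it in the same direction, and with a library left out 282 of 444 kept it and 162 lost it. List medians called between Wagyu and Brahman kept the call in 57 of 64 recalculations, all of which changed only the pseudocount. That tally leaves out the estimated correlation and fry, by each of which 0 of the 32 calls held. With a library left out, called list medians, some of them of other contrasts, kept the call in 394 of 468, with 60 lost and 14 reversed. Counts per class stayed within 1.5 times in 139 of 225 recalculations and, with a library left out, in 58 of 144. The cause was tested for none of the changes given here, except that a looser or stricter filter alters how many genes are adjusted together and the 4-library fit has fewer libraries. C3 holds the fewest cells of FAP-1 (156) and Granulocyte-1 (24). No paired analysis was possible because the labels pair no animals across breeds.

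Over the 6 classes, 14 genes, counted per class, were called between Wagyu and Brahman. The count was 3 with a pseudocount of 1, 2 with no filter, 7 with natural log values and 27 with the 4 libraries. It was 9 with an untrended prior, 24 by edgeR, 68 by DESeq2 and 2 for a slope over the Wagyu share. With a library left out it ran from 8 (C6) to 3080 (C4). Between Wagyu and crossbred 4 were called, against 1 with a pseudocount of 0.01, 0 with no filter, 2 with a filter at 0.2, 7 with natural log values, 2 with the 4 libraries, 8 by edgeR, 30 by DESeq2, 2 without the 10% of cells with most UMIs, and 2 (C3) to 13 (C6) with a library left out. Between crossbred and Brahman 77 were called, against 2 with no filter, 31 with natural log values, 47 with an untrended prior, 162 by DESeq2, and 33 (C3) to 3446 (C4) with a library left out. Against the mean of the pure breeds 29 were called, against 18 with a pseudocount of 0.01 and 14 (C2) to 57 (C6) with a library left out. The count of 0 genes whose effect differed between FAP-1 and Non-VEndoC (limma, 415 at an unadjusted p under 0.05, no other tool run) ran from 0 to 168 (C4).

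Of list tests between Wagyu and Brahman, 32 passed camera, against 0 with an estimated correlation and 21 (C6) to 43 (C1) with a library left out.

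None of the genes that reversed between Wagyu and Brahman was called. In FAP-1, TGFB1 became -0.0033 with natural log values, -0.0856 by edgeR and -0.0858 by DESeq2, and LOX -0.0177, -0.0922 and -0.0958. In FAP-2, PDGFRA became -0.0285 with natural log values and PPARG -0.116 by edgeR. With a library left out, FAP-1 ranges were -0.0372 (C6) to 0.164 (C1) for ZNF423, -0.32 (C3) to 0.677 (C4) for DLK1, -0.0955 (C6) to 0.224 (C1) for TGFB1 and -0.0605 (C3) to 0.174 (C4) for LOX. FAP-2 ranges were -0.225 (C3) to 0.538 (C4) for PDGFRA, -0.194 (C3) to 0.703 (C4) for PPARG, -0.50 (C3) to 0.121 (C4) for ZNF423 and -0.318 (C4) to 1.03 (C3) for TGFB1.

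List medians that reversed with a library left out ranged in Non-VEndoC from -1.13 (C1) to 0.0483 (C6) for mitochondrially encoded genes and -0.385 (C1) to 0.049 (C6) for the ribosome. They ranged from -0.0346 (C3) to 0.309 (C4) for the CD3 T cell ribosome, -0.466 (C3) to 0.169 (C4) for LEndoC matrix degradation and -0.763 (C4) to 0.353 (C3) for LEndoC heat shock. Sarcomere medians ranged from -0.181 (C2) to 1.48 (C5) in FAP-2 between Wagyu and crossbred. Between crossbred and Brahman they ranged, from without C4 to without C3, from -2.61 to 0.237 in FAP-1, -2.49 to 0.29 in Non-VEndoC, -1.37 to 0.739 in FAP-2, -3.05 to 0.393 in CD3 T cells and -2.75 to 0.889 in LEndoC.

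The FAP share difference between Wagyu and crossbred, 9.97 points, became -4.085 among cells that are not immune, and ranged from -1.985 (C2) to 21.92 (C5). That between Wagyu and Brahman, -5.47, became -15.65 among cells that are not immune and -12.45 with the Neutrophil class counted among them, and ranged from -11.53 (C3) to 0.585 (C4). That between crossbred and Brahman, -15.44, became -11.57 and -8.366, and ranged from -27.4 (C5) to -3.485 (C2). The LEndoC difference between Wagyu and Brahman ranged from -1.432 (C4) to 2.926 (C3). The immune share difference between Wagyu and Brahman, -10.92 points, became -6.227 without the Neutrophil class, and that between crossbred and Brahman, 10.27 points, became 14.97.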

Other observations

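The tests in these 2 paragraphs were chosen after the data were seen. SC, VEndoC, MuC-1, CD4 T cell, B cell, natural killer cell and Mo/Ma hold too few cells in C3, so they were tested without it, with C4 as the lone Brahman library, assumed to vary like the others. In SC, 12 of 9192 genes were higher in Wagyu than in Brahman by limma and 1 was lower, with 115 at an unadjusted p under 0.05. IFI6 averaged 5.28 and 9.66 UMIs per 10000 in Wagyu C1 and C6 and 0.467 in C4 (limma log2 fold change 3.68 ± 0.41, adjusted p = 5.1e-08), and MX1 0.987 and 1.3 against 0.0825 (2.76 ± 0.54, limma adjusted p = 0.0101). Of sarcomere genes, TNNC1 was higher by 2.93, TPM2 by 2.58, MYL2 by 2.70, TNNT1 by 3.08 and ACTA1 by 2.035. As a list, sarcomere genes were higher in Wagyu SC (median 1.38, 17 of 20 positive). The same list was higher in each of the other 6 classes, with medians from 1.31 in Mo/Ma to 2.20 in CD4 T cells. In the 6 classes tested with C3, its median ran from -0.25 in FAP-1 to 0.66 in Granulocyte-1. ACTA1 averaged 10.7 in FAP-1 of C3, 0.856 in C4, 3.6 in C1 and 3.96 in C6. The sarcomere rises, in SC too, are thus against C4 alone and may depend on which Brahman library is kept. Of these classes, T, B and natural killer cells and Mo/Ma should not make these transcripts. Against crossbred, which does not involve C4, TNNC1 was higher in Wagyu SC by 1.93 (limma adjusted p = 0.0219) and MYL2 by 2.34 (limma adjusted p = 0.00934). The sarcomere list was also higher in Wagyu than in crossbred classes that should not make it, by 1.41 in Granulocyte-1, 1.45 in Non-VEndoC (0.71 by DESeq2), 1.08 in CD3 T cells and 1.17 in LEndoC (camera adjusted p = 2.61e-09 or less, adjusted p = 0.578 to 0.822 with an estimated correlation), with 0 members called by limma over all genes. Without C2 these were 0.51, 0.29, 0.08 and 0.21, and the last 3 lost the call (0.563, 0.165 and 0.642), as did CD3 T cells without C1 (0.245).

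In VEndoC, 5 of 8363 genes were higher in Wagyu than in Brahman by limma and 0 were lower, with 258 at an unadjusted p under 0.05 (no other tool was run). IDO1, an interferon-induced enzyme that breaks down tryptophan, averaged 7.97 and 24.5 UMIs per 10000 in C1 and C6, 13.8 and 45.7 in C2 and C5, and 0.345 in C4 (limma log2 fold change 4.98 ± 0.67, adjusted p = 0.013). The other genes, chosen like these after their values were seen, were IFI27 (3.61, limma adjusted p = 0.00159), ISG15 (3.73, limma adjusted p = 0.013), the chaperone CLU (3.09, limma adjusted p = 0.0172) and RPL15 (2.46, limma adjusted p = 0.0385). Interferon genes were higher as a list (median 1.42, 25 of 25 positive, 2 called over all genes and 12 adjusted over the list alone, camera adjusted p = 7.5e-26, adjusted p = 0.488 with an estimated correlation). MuC-1 gave 1 gene higher in Wagyu, SYT4 (0 UMIs in C4, limma adjusted p = 0.0326), and 1 lower. In CD4 T cells limma called 2 genes higher and 2 lower, with 323 at an unadjusted p under 0.05, and in B cells 2 higher and 1 lower, with 149, RPL15 among those higher in both (3.52, adjusted p = 0.00203, and 3.29, adjusted p = 0.00437). In natural killer cells and Mo/Ma limma called 0 genes, with 345 and 1202 at an unadjusted p under 0.05.

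SYT4 in C4 lay below all 4 Wagyu and crossbred libraries in 11 of the 12 classes other than FAP-1 with at least 20 cells in every library but C3, as a sequence difference would give. HBB averaged 15.9 in Non-VEndoC of C4, at or under 0.0064 in the other libraries. Tenocytes came from 2 libraries, with 79 cells in C4 and 12 in C1.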
